A study of Homo sapiens with 18 samples.

How the data were processed

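RNA of 18 libraries of the H9 line, 3 in each of 6 groups, was measured by sequencing. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected with oligo(dT), and stranded libraries were made by the dUTP method with adapters that carried unique molecular identifiers. Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, with no role or order given for each. The authors deposited a single table with 43317 genes and 36 columns of values, 18 of counts and 18 of FPKM, per the file headers. The deposited counts are whole numbers per gene without normalisation, and whether they count reads or fragments, and with which strand setting, is not stated. The deposited FPKM values were scaled by the authors to gene length and library size, with a denominator that is not stated. Gene IDs, symbols, coordinates and KEGG pathways were taken as the table gives them; the genome build is not named in the sources used here.

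Every column was mapped to a library by its header. The design, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The design foresaw limma on log2(FPKM + 1) and, if counts were in the table, edgeR in its place, and edgeR was therefore used. Counts of all 18 libraries were fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest) with 6 group means and 12 residual degrees of freedom; 25858 genes were tested and the common biological coefficient of variation was 0.224. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were shOGA against ctrl in each of the 3 states, the 3 pairs of ctrl states, and the 3 differences between knockdown effects. Levels in CPM were computed with TMM-scaled library sizes.

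The 29 gene lists, with 631 entries, cover naive, primed, shared core and 8-cell-like genes, markers of trophectoderm, amnion, primitive endoderm, mesendoderm, neural ectoderm and fibroblast feeders, targets of FGF-ERK, NODAL-activin, WNT and p53, interferon-stimulated, germline, imprinted and histone genes, DNA methylation and Polycomb factors, the O-GlcNAc and hexosamine pathway, cholesterol synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, heat shock, stress response and cell cycle genes. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists and the 3 knockdown comparisons together, and over the lists in each other comparison. The tests were repeated with an estimated correlation. Members were also adjusted over each list alone. Marker scores were the mean log2(FPKM + 1) of the naive and of the primed list per library, compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

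The named genes followed a rule. A panel that included OGA, OGT, KLF17, DPPA3, DPPA5, DNMT3L, SUSD2, KLF4, TFCP2L1, NANOG, POU5F1, SOX2, ZIC2, DUSP6, SFRP2, OTX2, DNMT3B, CD24 and THY1 was read in every comparison. To these were added the largest rises and falls among genes that passed the test, changed by at least 2-fold, had a mean FPKM of at least 5 in the higher group and no overlap between libraries of the groups (10% of genes have none by chance for 3 against 3), without clone or numbered names: up to 8 each per knockdown comparison, and fewer for ctrl states and, without the overlap condition, for differences of effects. Up to 4 members with the smallest adjusted p were taken from each list described. Genes linked to the Y chromosome and XIST were left out of the tables.

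Alternatives were limma on log2(FPKM + 1) over the 14663 genes with an FPKM of at least 1 in at least 3 libraries, a pseudocount of 0.1, no FPKM filter, quantile normalisation, TMM-type rescaling of FPKM, DESeq2 1.42.0, no filter on low counts, a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. After the data were seen, RLE size factors, a scaling of each chromosome on its own (mitochondrial genes were left unscaled), PXGL shOGA replicate 2 as the only shOGA library of its state (an arm without replicates, with spread from the other groups), the O-GlcNAc list without OGA, and mean FPKM of at least 5 for the correlations between states were added. KEGG pathways were tested with the hypergeometric distribution and Benjamini-Hochberg adjustment, over tested genes with a pathway in the table, also after the data were seen. Lists of erythroid genes, leukocyte genes and RNAs without a poly(A) tail were likewise written after the data were seen. Chromosome medians used genes with log2 CPM above 3, in windows of 15 Mb. Figures were drawn with matplotlib 3.10.9.

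The tools were tested on simulated counts for the naive knockdown comparison, of which edgeR tested 24747 genes. Known changes were given to genes with a mean fitted count of at least 20 in the naive libraries. Recovery of genes near the floor was therefore not tested. edgeR recovered 31 of 67 genes changed 1.5-fold (46.3%), 49 of 67 changed 2-fold (73.1%) and 55 of 66 changed 4-fold (83.3%), with 0 wrong signs and 8 false calls. DESeq2, on 24731 genes, recovered 47.8%, 73.1% and 86.4% of the same sets, with 28 false calls. limma, on 14886 genes, recovered 46.3%, 73.1% and 71.2%, with 18 false calls. At 0.05, camera called a simulated list of 20 genes all raised 1.5-fold and did not call a list of 20 unchanged genes. Simulated genes were drawn independently, so false list calls from correlated genes were not tested. Far fewer genes were changed in the simulation than the 30.4% called in the real naive comparison, so recovery there can differ. At depths of 51.4 to 71.4 M counts, 3 counts correspond to between 0.0583 and 0.0420 CPM per library.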

Results

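RNA of the H9 human embryonic stem cell line was sequenced in 18 libraries, 3 in each of 6 groups. The groups crossed 3 culture states with a short hairpin RNA against OGA (shOGA) or a control (ctrl, labelled as wild type). No group is named as a second hairpin or a rescue. Effects of lower OGA therefore cannot be told apart here from those of hairpin delivery or of separate culture. OGA removes O-linked N-acetylglucosamine (O-GlcNAc) from proteins, and OGT adds it. PXGL cells were kept in naive medium, which holds cells in a state like the preimplantation epiblast, on mouse feeder cells. The reprime cells were PXGL cells moved to primed medium, and the cells named H9P were labelled as treated with primed medium. Total counts per library were 70.3 to 71.4 M in PXGL ctrl, and 67.0, 51.4 and 68.2 M in PXGL shOGA replicates 1, 2 and 3. They were 69.6 to 70.6 M in reprime ctrl, 64.7 to 66.7 M in reprime shOGA, 67.9 to 69.6 M in H9P ctrl and 66.7 to 69.8 M in H9P shOGA. Per gene, replicates of a group differed by a chi-square of 9.24 to 14.6, except the pairs with PXGL shOGA replicate 2, at 31.1 and 39.6. Levels are counts scaled to library size (CPM), mean ± SD of 3 libraries. Changes are log2 fold changes with adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 25858 genes. List p values come from camera, adjusted in the same way. Nothing in the labels says whether replicates were separate cultures, so each p measures the spread between these libraries.

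OGA mRNA was lower in every shOGA library than in every ctrl library of its state. OGA (ENSG00000198408, chromosome 10, 101784443 to 101818465, in the table's coordinates, whose genome build is not named) stood at 79.3 ± 10.3 CPM against 359 ± 7.59 in PXGL cells, which is 22.1% of the ctrl level. In reprime cells it stood at 75.05 ± 7.32 against 253 ± 6.81 CPM (29.7%), and in H9P cells at 74.5 ± 2.19 against 242 ± 1.33 CPM (30.8%). The fitted changes were -2.18 (SE 0.0729), -1.75 (SE 0.0720) and -1.70 (SE 0.0718), with edgeR adjusted p = 1.68e-13, 1.32e-11 and 8.04e-13. The exact two-sided permutation test of 3 against 3 gave p = 0.1 in each state, the smallest it allows. OGT, the opposing enzyme, also fell in each state, by 0.82, 0.23 and 0.27 (edgeR adjusted p = 1.13e-12, 0.000299 and 7.52e-06). The fall of OGT in reprime cells lost its call when each chromosome was scaled on its own (edgeR adjusted p = 0.270, the highest over 17 alternatives, whose lowest was 1.20e-06).

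**Figure D1:**
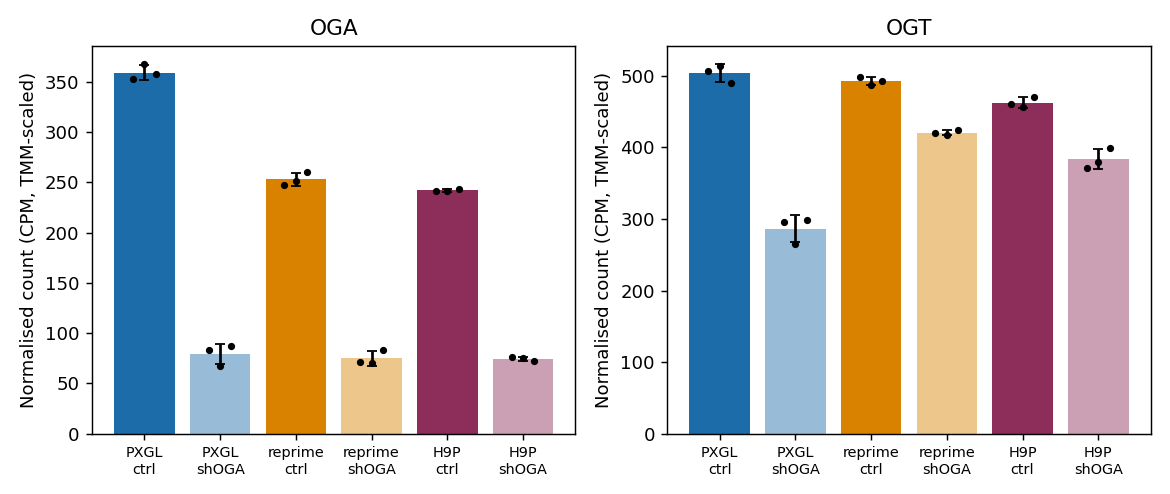
Normalised counts (CPM) of OGA and OGT in each of the 6 groups; bars are means of 3 libraries, error bars are SD and points are libraries. OGA lies between 67.7 and 87.2 CPM in PXGL shOGA libraries against a ctrl mean of 359 CPM.

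The ctrl libraries give the course of the naive to primed transition against which the knockdown was read. Mean log2(FPKM + 1) over 32 naive pluripotency markers was 5.24 ± 0.00896 in PXGL ctrl, 3.74 ± 0.00325 in reprime ctrl and 1.79 ± 0.0149 in H9P ctrl. Over 30 primed markers it was 1.34 ± 0.0275, 3.39 ± 0.00856 and 3.79 ± 0.0191 (SD, n = 3 libraries each). Progress was read over genes called between H9P and PXGL ctrl, changed at least 2-fold, with log2 CPM above 3. In reprime ctrl cells the median gene among the 1189 of these that were higher in H9P ctrl had covered 74.0% of the difference. The median gene among the 1114 that were higher in PXGL ctrl had covered 59.7%. With shOGA these medians were 73.2% and 58.8%, also measured from PXGL ctrl to H9P ctrl and not from PXGL shOGA.

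**Figure D2:**
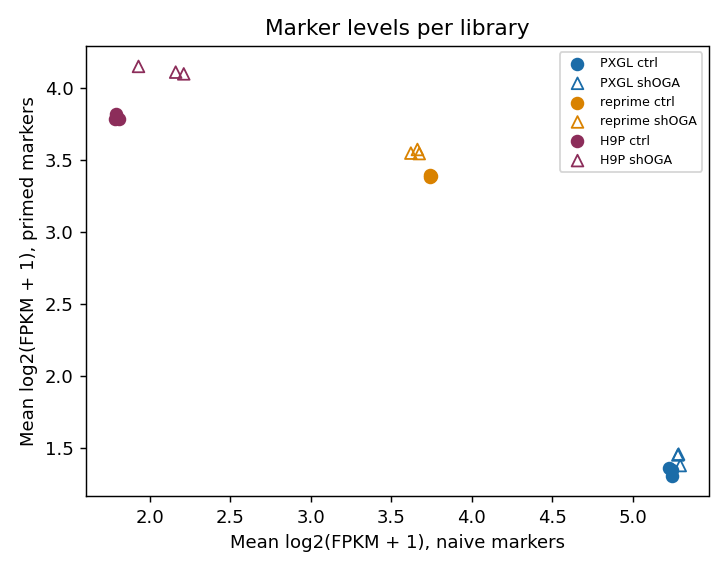
Mean log2(FPKM + 1) of the primed markers (vertical axis) against that of the naive markers (horizontal axis) in each of the 18 libraries. The reprime libraries lie between the PXGL libraries and the H9P libraries on the naive axis, and the H9P shOGA libraries lie above H9P ctrl on both axes.

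Putting naive ctrl cells in primed medium lowered regulators of the naive state and raised genes of the primed epiblast, of FGF signalling and of early lineages. KLF17, a transcription factor of the naive epiblast, fell from 53.6 ± 2.06 to 6.58 ± 0.0946 CPM (-3.02). KLF4, a pluripotency factor, fell from 103 ± 3.34 to 10.6 ± 1.24 CPM (-3.28) and DNMT3L, a cofactor of de novo DNA methylation, by 3.31. CD24, a surface marker of primed cells, rose from 98.5 ± 0.992 to 887 ± 5.34 CPM (3.17), and SFRP2, a secreted WNT modulator, from 1.91 ± 0.538 to 86.4 ± 1.502 CPM (5.49). THY1, another surface marker, rose by 5.92 and the epiblast factor ZIC2 by 4.64. OTX2, a factor of the formative and primed epiblast, was lower in reprime than in naive ctrl cells (4.97 ± 1.00 against 11.9 ± 1.12 CPM, -1.26). TBXT, the mesoderm factor brachyury, rose from 0.299 ± 0.0704 to 26.7 ± 0.739 CPM (6.47) and VIM, an intermediate filament of mesenchymal cells, from 5.18 ± 0.713 to 432 ± 4.88 CPM (6.38). NRK, a placental kinase, rose by 7.13. The largest falls among genes chosen by rule were those of SPIC (-7.93), PRAP1 (-6.93), OLAH (-6.06), ITGAM (-6.00) and FAM151A (-5.94).

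Of 32 naive markers 27 fell and 2 rose in reprime ctrl cells (camera adjusted p = 1.96e-10), and of 29 measured primed markers 28 rose and 1 fell (1.47e-108). All 18 FGF-ERK targets, which report MEK activity that naive medium blocks, rose (1.38e-62), with SPRY4 at 6.28, ETV1 at 4.57 and MYC at 3.75. Glycolysis rose in 21 of 22 genes and fell in 1 (2.42e-50), HK1 by 3.53, SLC2A1 by 3.64 and LDHA by 1.97. Mesendoderm markers rose in 12 of 14 genes (0.00206; CXCR4 by 4.48, LHX1 by 5.35, CER1 by 4.86). Trophectoderm markers rose in 15 of 24 with 2 lower (0.000100; KRT18 by 4.07) and fibroblast feeder markers in 18 of 22 (4.47e-12; TNC by 6.01, FN1 by 0.97). Stress response genes fell in 16 of 22 and rose in 4 (3.60e-08; TRIB3 by 2.64, ASNS by 1.55). The primitive endoderm list (9 of 17 higher and 4 lower, 0.00505) and the shared pluripotency core (10 of 15 higher and 5 lower, 0.00150) were also called. Each lost its call when FPKM was tested instead (highest adjusted p 0.241 and 0.0958 over 12 alternatives each, lowest 0.00164 and 0.000144). Mitochondrially encoded mRNAs fell in 11 of 13 genes and rose in 1 (5.23e-13), and their share of all counts went from 8.15 to 8.55% in PXGL ctrl to 4.44 to 4.67% in reprime ctrl libraries. Of the 14 lists called, 3 lost the call with an estimated correlation. Nuclear oxidative phosphorylation genes, 35 of 48 lower and 3 higher (4.49e-05), had adjusted p = 0.280 with an estimated correlation. The O-GlcNAc pathway, 7 of 16 higher and 4 lower (0.0156), and imprinted genes, 11 of 24 higher and 6 lower (0.0177), had adjusted p = 0.0688 and 0.0924 with an estimated correlation. In all, edgeR called 7205 genes higher and 5867 lower, 4379 and 1603 of them by at least 2-fold; the share called higher was 55.1%, and 44.8% after quantile normalisation of FPKM.

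H9P ctrl cells differed from naive ctrl cells more widely. All 32 naive markers were lower (camera adjusted p = 1.25e-44). DNMT3L differed by -8.74 and DPPA5, an RNA-binding protein of naive cells, stood at 9.31 ± 0.213 against 365 ± 22.6 CPM (-5.29). DPPA3, which protects DNA methylation patterns in the early embryo, stood at 30.3 ± 1.92 against 497 ± 26.5 CPM (-4.03). Primed markers were higher in 28 of 29 genes (1.59e-87), FGF-ERK targets in 18 of 18 (2.42e-41), glycolysis in 21 of 22 (4.09e-31) and cholesterol biosynthesis in 23 of 23 (9.27e-22; SC5D by 2.32, HMGCS1 by 1.92). NODAL-activin targets were lower in 9 of 13 and higher in 2 (8.78e-07; NODAL itself by -4.23, LEFTY2 by -4.12). Feeder markers were higher in 17 of 22 and lower in 1 (4.48e-06), and the shared core was higher in 9 of 15 and lower in 4 (2.28e-05). The core list lost its call on FPKM (highest adjusted p 0.113 over 12 alternatives, lowest 8.06e-08). KHDC1L, a gene of naive cells, stood at 0.0323 CPM against 409 ± 21.9, EDNRB, the endothelin receptor B, at 114 against 0.379 CPM, and the germline gene BRDT differed by -7.69. SEMG1, with 0 counts in naive ctrl, was at least 1029-fold higher in H9P ctrl. SPIC and FRG1FP, with 0 counts in H9P ctrl, were at least 1242-fold and 595-fold lower, against a floor of 3 counts over the group that covers counting error only. Of 14 lists called, 6 lost the call with an estimated correlation. Germline genes, 6 of 21 higher and 11 lower (0.00211), had adjusted p = 0.0517 with an estimated correlation, and imprinted genes, 15 of 24 higher and 5 lower (0.0214), had 0.119. Mitochondrially encoded mRNAs, 10 of 13 lower and 1 higher (7.31e-07), had adjusted p = 0.182 in that test, and neural ectoderm markers, 10 of 15 higher and 0 lower (0.0188), had 0.0505. Nuclear oxidative phosphorylation genes, 37 of 48 lower and 6 higher (0.000167), had adjusted p = 0.383 in it, and ribosomal protein genes, 32 of 36 lower and 0 higher (0.00129), had 0.566. edgeR called 8418 genes higher and 7065 lower, 5634 and 2917 of them by at least 2-fold. The median over all genes was 0.13, which the changes can be read against. Genes of chromosomes 6 and 18 had medians of -0.47 and -0.34.

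Reprime ctrl cells were compared with H9P ctrl cells to place the transition relative to an H9 culture in primed medium. Naive markers were higher in 26 of 32 genes and lower in 1 (camera adjusted p = 1.48e-61): DPPA5 stood at 240 against 9.31 CPM (4.69) and DPPA3 at 319 against 30.3 CPM (3.40). NODAL-activin targets were higher in 11 of 13 (6.09e-21; NODAL by 3.39, GDF3 by 1.86) and WNT targets in 12 of 15 (0.000154; SP5 by 2.77, BMP4 by 2.31). Mesendoderm markers were higher in 11 of 14 with 1 lower (0.000154; MIXL1 by 3.68, APLNR by 3.31). Trophectoderm markers were higher in 20 of 24 with 3 lower (3.79e-05) and germline genes in 10 of 21 with 2 lower (1.06e-05; BRDT by 7.54, SYCP3 by 7.00). CGA, the alpha subunit of placental and pituitary hormones, stood at 8.29 CPM against 0 counts, at least 570-fold higher. Cholesterol biosynthesis was lower in 23 of 23 genes (1.06e-44; HMGCS1 by -1.82, LSS by -1.68), and primed markers in 15 of 29 with 6 higher (3.79e-05; OTX2 by -2.00). The shared core was lower in 9 of 15 with 5 higher (0.00124; highest adjusted p 0.276 over 12 alternatives, on FPKM, lowest 9.59e-06) and stress response genes in 12 of 22 with 6 higher (2.65e-05). OGA differed by 0.06 (edgeR adjusted p = 0.511) and ZIC2 by 0.05 (0.809). Ribosomal protein genes, 32 of 36 higher (1.78e-06), had adjusted p = 0.381 with an estimated correlation, and neural ectoderm markers, 6 of 15 lower (0.0283), had 0.0517. edgeR called 5647 genes higher and 5412 lower, 51.1% of them higher, and 38.3% without a filter on low FPKM. Whole chromosomes stood apart here, with medians of 0.38 on chromosome 6 and 0.37 on chromosome 18.

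In naive cells the question was what lower OGA changes before the transition. Replication-dependent histone genes and heat shock genes rose as lists, DNA methylation genes did so with members in both directions, and DUSP6 and SFRP2, already low, fell further. Naive markers did not pass the list test, nor did FGF-ERK targets, with 5 of 18 higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.243). H1-2, a linker histone, rose from 3.62 ± 0.491 to 16.9 ± 1.66 CPM (2.23, edgeR adjusted p = 2.77e-09), and HSPA8, a constitutive chaperone, from 1079 ± 19.2 to 1921 ± 128 CPM (0.83, edgeR adjusted p = 2.24e-13). DNMT3B, a de novo DNA methyltransferase, rose from 703 ± 9.05 to 1063 ± 18.7 CPM (0.60, edgeR adjusted p = 9.75e-13). SFRP2 fell from 1.91 ± 0.538 to 0.228 ± 0.185 CPM (-2.98, edgeR adjusted p = 1.58e-06) and DUSP6, a phosphatase induced by ERK, from 1.22 ± 0.413 to 0.357 ± 0.196 CPM (-1.79, edgeR adjusted p = 0.000540). Among naive genes DPPA3 fell from 497 ± 26.5 to 324 ± 8.49 CPM (-0.62) and DPPA5 rose by 0.22. KLF17 differed by 0.26 (edgeR adjusted p = 0.418), KLF4 by 0.19 (0.0582), NANOG by -0.11 (0.0601) and TFCP2L1 by 0.04 (0.648).

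Of 21 measured histone genes 15 rose and 0 fell in naive shOGA cells (17 and 0 adjusted over the list alone; camera adjusted p = 4.98e-08), with H2BC11 at 2.33, H4C14 at 1.37 and H2AC6 at 1.27. Histone genes are near-identical copies, so single members are uncertain. Transcripts without a poly(A) tail, a list written after the data were seen, rose in the same comparison: 5 of 10 such RNAs rose and 0 fell (median 1.46). That list holds RN7SK and RMRP, which are among the largest rises of this comparison, so it is no independent line of evidence. The libraries were selected for poly(A) RNA, and whether that selection has a part in the rise of histone genes was not tested. RN7SK, the scaffold RNA of a transcription elongation regulator (ENSG00000283293, chromosome 6, 52995621 to 52995948), stood at 5.89, 9.31 and 1.43 CPM in shOGA replicates 1, 2 and 3 against 0.246 ± 0.110. RMRP, an RNA of ribosomal RNA processing, stood at 2.95 ± 2.03 against 0.0342 ± 0.0592 CPM. The ribosomal RNA genes RNA5-8SN1 and RNA5-8SN3 and the microRNA genes MIR3648-1 and MIR3648-2, each a pair of near-identical copies, had changes of 3.52, 3.38, 3.49 and 3.46. Heat shock genes rose in 8 of 12 and fell in 1 (8 and 2 adjusted over the list alone; 5.28e-09), HSPA1A by 1.12, HSPA1B, its near-identical copy, by 1.09 and DNAJA1 by 0.39. DNA methylation genes rose in 8 of 15 and fell in 3 (9 and 3 adjusted over the list alone; 0.000556), UHRF1, which recruits DNMT1, by 0.67, DNMT1 by 0.53 and MBD3 by 0.78. Trophectoderm markers rose in 8 of 24 with 0 lower (8 and 0 adjusted over the list alone; 0.000820; KRT8 by 0.85, KRT19 by 0.49). Fibroblast feeder markers rose in 8 of 22 with 1 lower (8 and 1 adjusted over the list alone; 0.000193), FN1 from 176 ± 3.13 to 329 ± 12.2 CPM (0.90) and TAGLN by 1.28. The feeder list lost its call on FPKM, where the highest adjusted p over 13 alternatives was 0.159 and the lowest 8.56e-08. O-GlcNAc and hexosamine genes were called lower as a list that holds OGA itself, with 7 of 16 lower and 6 higher (8 and 6 adjusted over the list alone; 0.00255). GFPT1, the rate-limiting enzyme of hexosamine synthesis, changed by -0.65 and HCFC1, a heavily O-GlcNAc-modified regulator, by 1.00. Without OGA the call was lost (6 of 15 lower and 6 higher, camera adjusted p = 0.317), and it ended on FPKM (highest adjusted p 0.509, lowest 0.00140 over 14 alternatives). NODAL-activin targets rose in 6 of 13 with 1 lower (7 and 4 adjusted over the list alone; 0.0113, and adjusted p = 0.111 with an estimated correlation), SMAD7 by 0.82 and LEFTY1 by 0.66. Amnion markers rose in 3 of 9 with 0 lower (3 and 0 adjusted over the list alone; 0.0454, and adjusted p = 0.0941 with an estimated correlation), IGFBP3 by 1.19 and HEY1 by 1.24. The amnion call was lost in 8 of 13 alternatives (lowest adjusted p 0.0165, highest 0.298), among them those without PXGL ctrl replicate 3, PXGL shOGA replicate 1 and PXGL shOGA replicate 3.

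The primed list had 10 of 29 members higher and 11 lower in naive shOGA cells (11 and 11 adjusted over the list alone; camera adjusted p = 0.0793), and the naive list 5 of 32 higher and 4 lower (5 and 4 adjusted over the list alone; 0.349). The naive score rose by 0.05 and the primed score by 0.09, each with p = 0.1 in the exact two-sided permutation test and 0.1 after Benjamini-Hochberg adjustment over 12 score tests. With a pseudocount of 0.1 the primed difference turned to -0.018. GTSF1, a PIWI pathway factor, fell from 40.5 ± 1.43 to 11.4 ± 1.39 CPM (-1.83) and DYSF, a membrane repair protein, from 83.1 ± 0.325 to 29.1 ± 2.09 CPM (-1.51). Other falls chosen by rule were those of OXSM (-1.54), FGD4 (-1.43), C5orf34 (-1.33), ALMS1-IT1 (-1.22) and RBP7 (-1.19). The alpha globin genes HBA1 and HBA2, near-identical copies, had changes of 5.89 and 5.97 that came from shOGA replicates 1 and 3. HBA2 (ENSG00000188536, chromosome 16, 172876 to 173710) stood there at 123 and 117 CPM against 3.18 in replicate 2 and 1.29 ± 0.330 in ctrl. With replicate 2 as the only shOGA library, spread came from the other groups alone, so only effect sizes are given. Histone genes had a median of 1.77 and the feeder list one of -0.037. Whether either list keeps its call cannot be read from a median. Among lists not called with all libraries, ribosomal protein genes had 0.14, nuclear oxidative phosphorylation genes 0.16 and mitochondrially encoded mRNAs -0.22. In all, edgeR called 3883 genes higher and 3973 lower, 803 and 526 of them by at least 2-fold. Calls of HBA1, HBA2 and FGD4 ended when only the compared groups were fitted (edgeR adjusted p = 0.0637, 0.0638 and 0.0639, the highest of 18 alternatives, with lowest values of 1.10e-13, 1.88e-16 and 7.56e-17). That of RMRP ended with DESeq2 (adjusted p = 0.121, highest of 18, lowest 3.49e-05). On FPKM the calls of IGFBP3 and TNC ended (highest adjusted p 0.125 and 0.180, lowest 1.75e-06 and 1.12e-10), and HEY1 reached 0.515 (lowest 8.67e-05).

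After naive cells were moved to primed medium, which is the transition the series is about, shOGA cells held more RNA of mesendoderm, primitive endoderm, FGF-ERK and cell cycle genes than ctrl cells. APLNR, the apelin receptor of early mesoderm (ENSG00000134817, chromosome 11, 57233577 to 57237235), rose from 7.92 ± 0.783 to 42.2 ± 1.18 CPM (2.41, SE 0.196, edgeR adjusted p = 4.20e-08). CER1, a secreted NODAL and BMP antagonist of anterior endoderm (ENSG00000147869, chromosome 9, 14719724 to 14722733), rose from 21.4 ± 0.551 to 79.0 ± 4.60 CPM (1.89, SE 0.211, edgeR adjusted p = 2.03e-05). MIXL1, a primitive streak factor, rose from 16.2 ± 1.15 to 45.6 ± 0.794 CPM (1.49, edgeR adjusted p = 0.000326). GATA6, a factor of primitive endoderm, rose from 3.56 ± 0.330 to 14.3 ± 0.624 CPM (2.01, edgeR adjusted p = 2.05e-05). DUSP6 (ENSG00000139318, chromosome 12, 89347235 to 89352501) rose from 15.8 ± 1.40 to 60.7 ± 4.18 CPM (1.94, SE 0.142, edgeR adjusted p = 3.61e-07). OTX2 rose from 4.97 ± 1.00 to 13.7 ± 0.908 CPM (1.46, SE 0.123, edgeR adjusted p = 2.89e-08).

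Mesendoderm markers rose in 6 of 14 with 0 lower in reprime shOGA cells (9 and 0 adjusted over the list alone; camera adjusted p = 6.42e-11; LHX1 by 2.41). Primitive endoderm markers rose in 8 of 17 with 0 lower (10 and 0 adjusted over the list alone; 1.91e-11; PDGFRA by 1.39, FLRT3 by 1.07, LAMA1 by 0.47). FGF-ERK targets rose in 8 of 18 with 0 lower (9 and 0 adjusted over the list alone; 1.05e-10; CCND1 by 0.45, SPRY4 by 0.41, MYC by 0.32). WNT targets rose in 6 of 15 with 0 lower (7 and 0 adjusted over the list alone; 0.000556; LGR5 by 2.51, SP5 by 0.79, NKD1 by 0.69). Cell cycle genes rose in 17 of 30 with 1 lower (19 and 1 adjusted over the list alone; 7.27e-10; AURKA by 0.34, RRM2 by 0.30, MCM7 by 0.28), and cholesterol biosynthesis genes did so in 13 of 23 with 1 lower (15 and 2 adjusted over the list alone; 7.27e-10; ACAT2 by 0.48, FDFT1 by 0.34). Primed markers rose in 8 of 29 and fell in 3 (10 and 4 adjusted over the list alone; 4.98e-08; ZIC2 by 0.84 and HMGA2 by 0.67, against NLGN4X at -0.95). The shared pluripotency core was lower in 5 of 15 and higher in 1 (5 and 2 adjusted over the list alone; 0.00127; ESRG by -0.67, PRDM14 by -0.30, DPPA4 by -0.28). O-GlcNAc genes were lower in 4 of 16 with 3 higher (5 and 4 adjusted over the list alone; 0.00360), a call lost without OGA (adjusted p = 0.630, the highest of 13 alternatives, lowest 0.00215). On FPKM the primed, core and O-GlcNAc lists lost their calls, with highest adjusted p of 0.0785 and 0.0765 for the primed and core lists over 12 alternatives and lowest of 1.19e-09 and 8.87e-06. Glycolysis was lower in 7 of 22 and higher in 3 (10 and 4 adjusted over the list alone; 0.00595, and adjusted p = 0.329 with an estimated correlation; HK2 by -0.40). Trophectoderm markers rose in 6 of 24 with 1 lower (7 and 1 adjusted over the list alone; 0.0194, and adjusted p = 0.0812 with an estimated correlation), KRT19 by 0.31 while ELF3 fell by 0.58. Polycomb genes rose in 4 of 24 with 1 lower (5 and 1 adjusted over the list alone; 0.0266, and adjusted p = 0.0539 with an estimated correlation). The 8-cell-like genes were lower in 1 of 9, CCNA1 (-0.73), with 0 higher (2 and 0 adjusted over the list alone; 0.0455, and adjusted p = 0.104 with an estimated correlation). The 8-cell-like call ended in 9 of 12 alternatives (lowest adjusted p 0.0369, highest 0.245), among them each of those that left out 1 library.

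Other rises in reprime shOGA cells included CGA (1.69), CYP1B1, a retinoid and steroid metabolising enzyme, from 34.3 ± 0.764 to 106 ± 2.05 CPM (1.62), NTS, the neurotensin precursor, (1.56) and HAS2, a hyaluronan synthase, (1.40). MAGEB2, a cancer-testis gene, fell from 11.97 ± 0.348 to 3.12 ± 0.183 CPM (-1.94). AASS, an enzyme of lysine breakdown (ENSG00000008311, chromosome 7, 122073549 to 122144255), fell from 268 ± 2.92 to 115 ± 0.631 CPM (-1.22), and LAMB3 (-1.16), NRN1 (-1.11), NPPB (-1.10) and OLFML3 (-1.04) fell as well. The naive list had 6 of 32 higher and 5 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.640), with KLF17 at -0.67 (edgeR adjusted p = 0.0944), DPPA3 at 0.10 (0.694) and NANOG at -0.06 (0.462). The naive score fell by 0.09 and the primed score rose by 0.17 (exact two-sided permutation p = 0.1 each, and 0.1 after adjustment). Histone genes, with 0 of 21 called in either direction by edgeR, had camera adjusted p = 0.810. edgeR called 1529 genes higher and 1540 lower, 136 and 172 of them by at least 2-fold. Genes of chromosome 12, which holds DUSP6, had a median of 0.22 in this comparison.

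**Figure D3:**
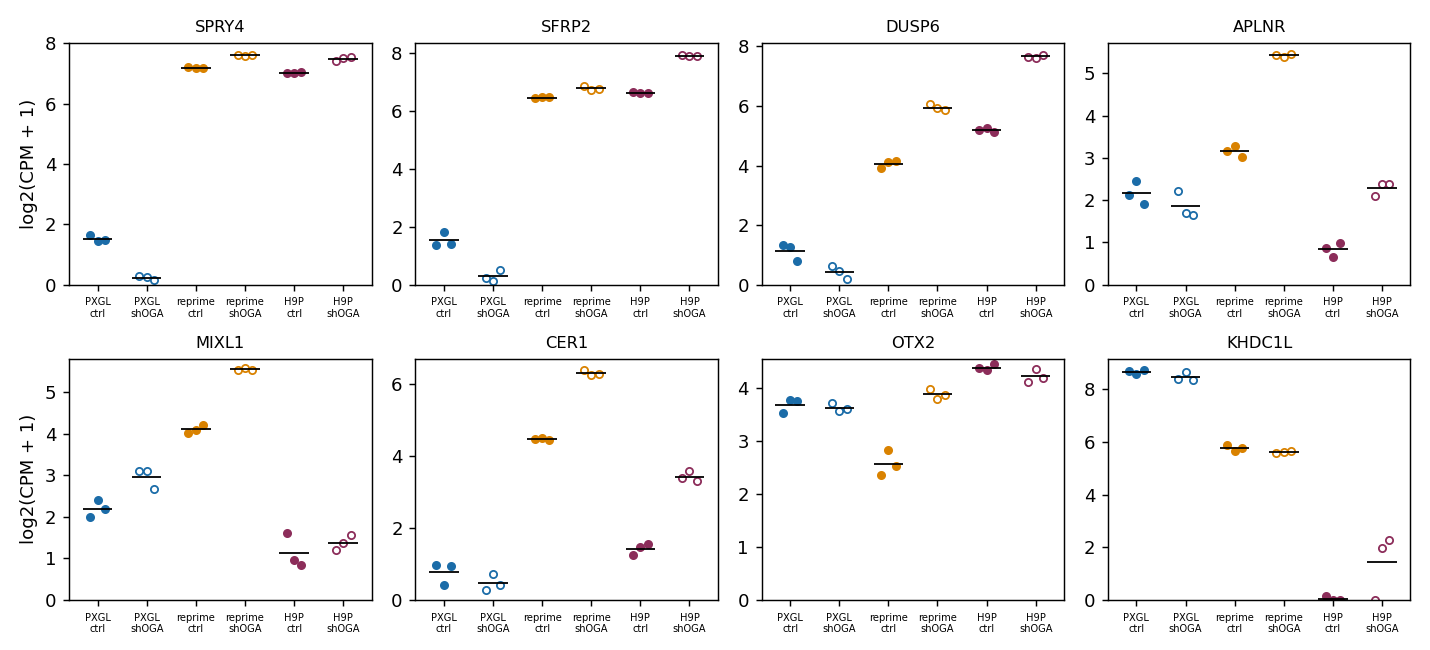
log2(CPM + 1) of 8 genes in each library; points are libraries and lines are means of 3 libraries per group. SPRY4, SFRP2 and DUSP6 are lower in PXGL shOGA than in PXGL ctrl, while APLNR, MIXL1, CER1 and OTX2 are higher in reprime shOGA than in reprime ctrl.

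In H9P cells the knockdown was read in an H9 culture in primed medium that had not come from the PXGL libraries by any label. FGF-ERK, cholesterol and NODAL genes rose and the shared pluripotency core fell. Mitochondrial genes fell too, in list calls that an estimated correlation ended (adjusted p = 0.108 for those encoded in mitochondria and 0.178 for nuclear ones). DUSP6 rose from 35.7 ± 1.62 to 202 ± 7.37 CPM (2.50, SE 0.140, edgeR adjusted p = 1.78e-09). BRDT, a testis bromodomain protein (ENSG00000137948, chromosome 1, 91949371 to 92014426), rose from 0.793 ± 0.251 to 41.4 ± 0.329 CPM (5.70, SE 0.106, edgeR adjusted p = 1.87e-19). KHDC3L, an oocyte factor (ENSG00000203908, chromosome 6, 73362658 to 73364171), rose from 0.682 ± 0.140 to 16.6 ± 0.926 CPM (4.60, edgeR adjusted p = 4.34e-14). DPPA5, which lies beside KHDC3L on chromosome 6, rose from 9.31 ± 0.213 to 57.8 ± 4.54 CPM (2.63, edgeR adjusted p = 7.79e-19). DPPA3 fell from 30.3 ± 1.92 to 13.8 ± 3.33 CPM (-1.13, edgeR adjusted p = 3.78e-06) and NANOG from 124 ± 3.42 to 91.3 ± 3.30 CPM (-0.45, edgeR adjusted p = 3.30e-08).

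Of 18 FGF-ERK targets 15 rose and 1 fell in H9P shOGA cells (16 and 1 adjusted over the list alone; camera adjusted p = 9.17e-11; PHLDA1 by 0.69, CCND1 by 0.62, MYC by 0.61). Of 23 cholesterol genes 18 rose and 2 fell (18 and 2 adjusted over the list alone; 5.31e-11; ACAT2 by 0.86, INSIG1 by 0.67). NODAL-activin targets rose in 7 of 13 with 2 lower (7 and 2 adjusted over the list alone; 1.75e-08; NODAL by 1.26, LEFTY1 by 1.08, against TDGF1, a NODAL co-receptor, at -0.79). Primed markers rose in 14 of 29 with 5 lower (17 and 5 adjusted over the list alone; 3.24e-06), SALL3 by 1.48, SFRP2 by 1.28 and HMGA2 by 1.00 while DNMT3B fell from 1725 ± 39.4 to 1103 ± 32.1 CPM (-0.65). Naive markers rose in 13 of 32 with 6 lower (14 and 6 adjusted over the list alone; 6.63e-07, and adjusted p = 0.102 with an estimated correlation), KLF5 by 1.12 and SUSD2 by 0.75; KLF17 stood at 0.366 ± 0.267 against 0.0365 ± 0.0316 CPM. Feeder markers rose in 9 of 22 with 2 lower (10 and 2 adjusted over the list alone; 0.000194; TWIST1 by 2.57, TAGLN by 1.87, FN1 by 0.92). The unfolded protein and integrated stress response list rose in 10 of 22 with 5 lower (11 and 5 adjusted over the list alone; 0.00226, and adjusted p = 0.0566 with an estimated correlation), ATF3 by 0.80 and ASNS by 0.70. Core genes were lower in 11 of 15 and higher in 2 (11 and 2 adjusted over the list alone; 5.40e-05), DPPA4 by -0.50. Mitochondrially encoded mRNAs were lower in 9 of 13 with 0 higher (9 and 0 adjusted over the list alone; 2.74e-09, and adjusted p = 0.108 with an estimated correlation), and took 3.81 to 3.90% of counts against 4.66 to 4.98%. Nuclear oxidative phosphorylation genes were lower in 35 of 48 with 6 higher (35 and 6 adjusted over the list alone; 5.14e-08, and adjusted p = 0.178 with an estimated correlation; COX7C by -0.71, NDUFA9 by -0.53). Ribosomal protein genes were lower in 20 of 36 with 2 higher (20 and 2 adjusted over the list alone; 0.000205, and adjusted p = 0.510 with an estimated correlation; RPS24 by -0.58, RPL7 by -0.36, members of a family with many pseudogenes). Heat shock genes were lower in 5 of 12 with 1 higher (5 and 1 adjusted over the list alone; 0.0148; HSPA8 by -0.46, HSPD1 by -0.42). O-GlcNAc genes were lower in 8 of 16 with 5 higher (8 and 5 adjusted over the list alone; 0.00996, and adjusted p = 0.0644 with an estimated correlation), GNPDA1 by -0.70 and GNPNAT1 by -0.47 while PGM3 rose by 0.72. That call was lost without OGA too (camera adjusted p = 0.216), and when each chromosome was scaled on its own. GNPDA1 lies on chromosome 5 and PGM3 on chromosome 6, whose genes shifted as a whole in this comparison. On FPKM the naive, NODAL-activin, heat shock, O-GlcNAc, stress response and primed lists lost their calls, with highest adjusted p between 0.0837 (NODAL-activin) and 0.234 (O-GlcNAc) over 12 alternatives, 13 for O-GlcNAc, and lowest between 6.70e-19 (naive) and 0.00609 (heat shock).

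Other rises in H9P shOGA cells were those of LCP1, an actin-bundling protein of leukocytes, from 18.6 ± 0.737 to 279 ± 2.13 CPM (3.91), C3orf56 (3.43), PPIAP46, a pseudogene of a cyclophilin family with many copies (2.62), and CER1 (2.53). Falls included CEND1, a neuronal cell cycle exit protein, from 12.999 ± 1.24 to 1.55 ± 0.617 CPM (-3.06), AASS from 619 ± 6.48 to 134 ± 1.06 CPM (-2.20), TCEAL5 (-2.16), PCDHB5 (-1.95), NAP1L6P (-1.75), NDUFA4L2 (-1.65) and RBMXL2 (-1.59). Mesendoderm markers, 5 of 14 higher and 1 lower (6 and 3 adjusted over the list alone), had camera adjusted p = 0.158. Germline, imprinted, interferon-stimulated, neural ectoderm and p53 target genes passed the list test with shOGA in none of the 3 states (camera adjusted p between 0.0722, for interferon-stimulated genes in reprime cells, and 0.935, for imprinted genes in H9P cells). The naive and primed scores rose by 0.31 and 0.32 (exact two-sided permutation p = 0.1 each, and 0.1 after adjustment). edgeR called 4389 genes higher and 4004 lower, 1076 and 672 of them by at least 2-fold.

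Whole chromosomes stood apart in the same comparison. The median change over 538 genes of chromosome 6 was 0.57, with 95.2% of them above 0, and those of chromosomes 12, 18 and 5 were 0.35, 0.30 and -0.35. Of the 4389 genes called higher, 617 (14.1%) lay on chromosome 6, which held 5.24% of the genes tested. POU5F1, the pluripotency factor OCT4, and CD24, both on chromosome 6, rose by 0.47 and 0.32 (edgeR adjusted p = 4.80e-11 and 1.40e-09) under the single scaling per library. They had -0.078 and -0.23 when each chromosome was scaled on its own. LIN28B, also there, went from 0.54 to -0.012 and RPS23, on chromosome 5, from -0.36 to 0.014. DPPA5 and KHDC3L lie on chromosome 6 and DUSP6 on chromosome 12. Other genes named for this comparison lie on shifted chromosomes too. ACAT2 and PGM3 are on chromosome 6, HMGA2 and PHLDA1 on 12, SALL3 on 18, and GNPDA1, COX7C and PCDHB5 on 5. DPPA3, NANOG and NDUFA9 lie in the first 15 Mb of chromosome 12, where the median was -0.15, so they fell in the direction of their region. NDUFA4L2, in the window of 45 to 60 Mb with a median of 0.43, fell against its region.

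**Figure D4:**
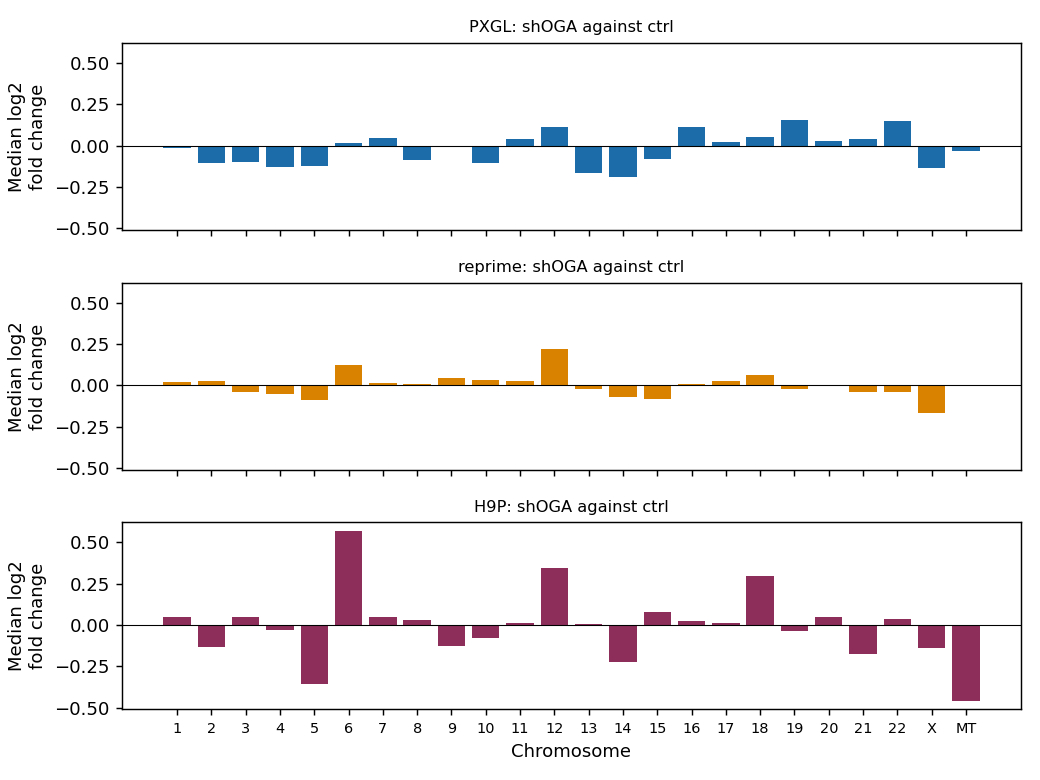
Median log2 fold change of shOGA against ctrl over the genes of each chromosome, in PXGL, reprime and H9P cells; each bar is a chromosome and MT is the mitochondrial genome. In H9P cells chromosome 6 stands at 0.57 and chromosome 5 at -0.35.

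Whether the knockdown acted differently in the 3 states was tested as the difference of its effects. DUSP6, SPRY4, which restrains receptor tyrosine kinase signalling, and SFRP2 fell with shOGA in naive cells, where SPRY4 had a change of -3.44 (edgeR adjusted p = 3.23e-13), and DUSP6 and SPRY4 rose in reprime cells. The effect in reprime cells minus that in naive cells was 3.73, 3.85 and 3.29 (edgeR adjusted p = 1.75e-06 for DUSP6 and 3.34e-13 for SPRY4). SPRY4 stood at 1.88 and 0.174 CPM in PXGL ctrl and shOGA, 146 and 194 CPM in reprime cells, and 129 and 179 CPM in H9P cells. Between reprime and naive cells edgeR called 5926 genes, 3015 with a more positive and 2911 with a more negative effect. Mesendoderm (6 of 14 more positive, 1 more negative, camera adjusted p = 0.00628), primitive endoderm (7 of 17 and 0, 0.00355) and cholesterol genes (11 of 23 and 2, 0.000932) had more positive effects in reprime cells. Among them were APLNR at 2.80, CER1 at 2.83 and LHX1 at 3.39. Histone (0 of 21 more positive and 10 more negative, 1.96e-05), heat shock (2 of 12 and 8, 1.96e-05) and feeder genes (2 of 22 and 10, 0.00130) had more negative ones. RN7SK, an RNA without a poly(A) tail, also had a more negative effect (-3.87). The part of poly(A) selection in the histone difference was not tested. With replicate 2 as the only naive shOGA library the feeder median went from -0.89 to -0.12. The other 6 of 12 lists lost the call with an estimated correlation: DNA methylation (adjusted p = 0.0541 with an estimated correlation), NODAL-activin (0.167), glycolysis (0.364), imprinted (0.167), mitochondrially encoded (0.548) and core genes (0.0650).

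Between H9P and naive cells the effect differed for 7673 genes, more positive for 4137 and more negative for 3536. FGF-ERK targets (12 of 18 more positive and 3 more negative, camera adjusted p = 0.000310) and cholesterol genes (13 of 23 and 1, 1.65e-08) had more positive effects in H9P cells. Heat shock (2 of 12 more positive and 10 more negative, 1.10e-09), histone (0 of 21 and 9, 0.00165) and core genes (2 of 15 and 10, 5.42e-05) had more negative ones there. DPPA5 differed by 2.42 and DNMT3B by -1.24. Lists that lost the call with an estimated correlation were NODAL-activin (adjusted p = 0.227 with an estimated correlation), mitochondrially encoded (0.344), naive (0.227), nuclear oxidative phosphorylation (0.227) and ribosomal protein genes (0.501). Between reprime and H9P cells 5056 genes differed, 2152 more positive and 2904 more negative in reprime cells. There the effect on OTX2 was more positive by 1.63 and that on DPPA5 more negative, at -2.84. Effects were more negative in reprime cells for NODAL-activin targets (3 of 13 more positive and 6 more negative, camera adjusted p = 4.58e-10), FGF-ERK targets (1 of 18 and 7, 0.00295) and feeder markers (1 of 22 and 6, 0.000147). They were more positive for heat shock genes (4 of 12 and 0, 0.00187). Another 8 lists lost the call with an estimated correlation: cell cycle (adjusted p = 0.0526 with an estimated correlation), cholesterol (0.0526), naive (0.0526), mitochondrially encoded (0.0701), nuclear oxidative phosphorylation (0.167), ribosomal protein (0.363), core (0.120) and stress response genes (0.136).

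**Figure D5:**
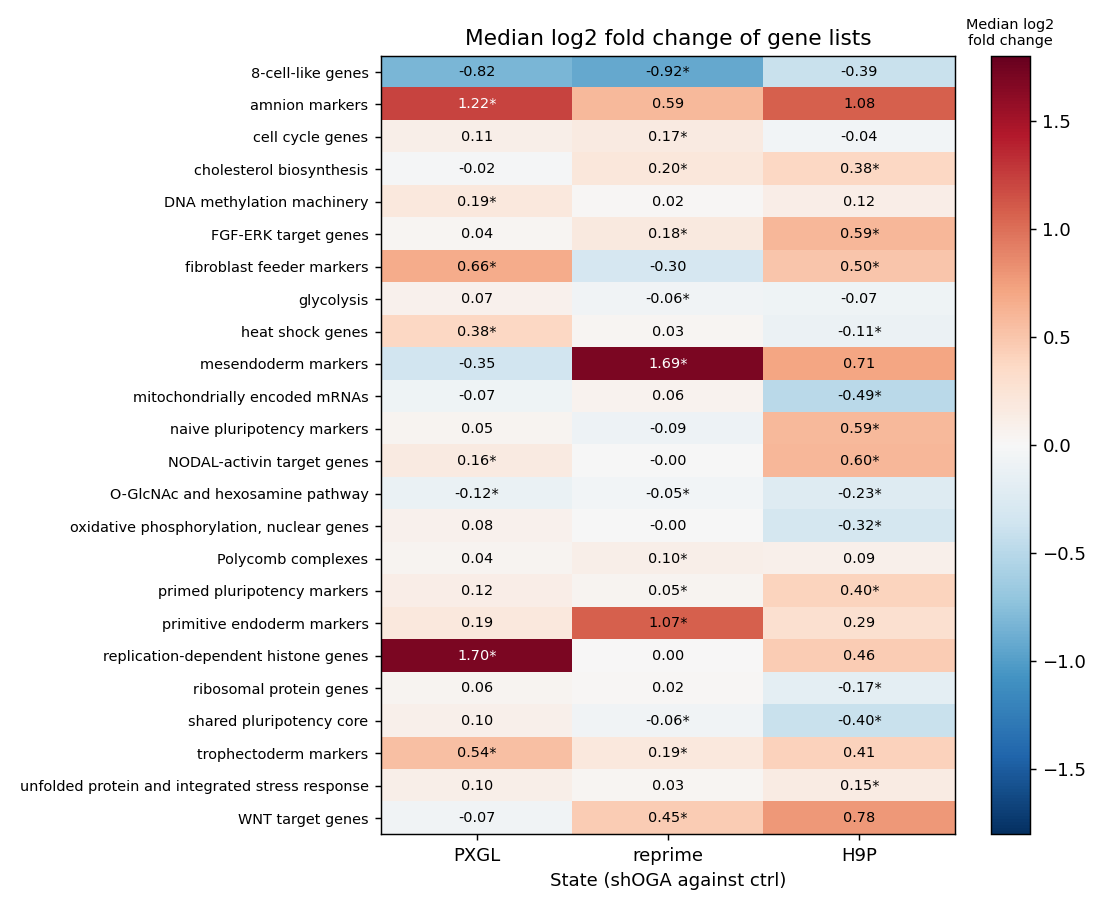
Median log2 fold change of shOGA against ctrl over the measured members of each gene list called in at least 1 state, in PXGL, reprime and H9P cells; an asterisk marks a camera adjusted p under 0.05. Histone genes have a median of 1.70 in PXGL cells and 0.00 in reprime cells, and mesendoderm markers 1.69 in reprime cells.

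Knockdown effects were shared between reprime and H9P cells more often than lists of independent genes would be. For these states 945 genes rose in both where 260 would by independent lists, and 720 fell in both where 238 would. For naive and H9P cells 1225 genes rose in both (659 by independent lists) and 1331 fell in both (615), and for naive and reprime cells 492 rose (230) and 563 fell (237) in both. Genes called in opposite directions also exceeded independent lists for naive and reprime cells (295 against 231 and 401 against 235) and for naive and H9P cells (653 against 601 and 908 against 674). For reprime and H9P cells they numbered 130 against 237 and 273 against 261. Pearson's r of the changes across 25858 genes, which are not independent replicates, was 0.0630 for reprime and H9P, 0.0263 for naive and H9P and 0.0214 for naive and reprime cells, with Spearman's rho 0.168, 0.0719 and 0.0543. Over the 10396 genes with log2 CPM above 3 Pearson's r was 0.330, 0.129 and 0.0925. No libraries were shared between these comparisons. Genes of chromosome 12 shifted by position in all 3 states. Windows of 15 Mb from 45 Mb on had medians of 0.24 to 0.31 in reprime, 0.40 to 0.50 in H9P and 0.0065 to 0.34 in naive cells. Windows below 30 Mb had medians of -0.34 to -0.12 over these states. How much of the overlap of calls such a shared shift accounts for was not tested. In all 3 states 363 genes rose and 352 fell. MMP2, a matrix metalloprotease chosen after its values were seen, rose by 1.70, 1.03 and 1.23 and was, with OGA, called at 2-fold or more in all 3. The knockdown effect in reprime cells was also set against the difference of H9P from naive ctrl cells, to ask whether it followed the direction of the transition. Across 25858 genes Pearson's r was 0.00543 and Spearman's rho -0.0488, and over the 10396 genes -0.0657 and -0.0956.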

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

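Of the tests on explanations, those of chromosome dose and of scaling for the chromosome shifts, of the knockdown and of depth for the globin transcripts, and of scaling and foreign RNA for the primed genes were chosen only after the result was seen; the others were written before.

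The effect of shOGA differed between states, as tested by the difference of the effects in edgeR's quasi-likelihood test, for 5926 genes between reprime and naive cells, 7673 between H9P and naive cells and 5056 between reprime and H9P cells. For each of these, 100 splits that regrouped genotypes within both states were counted, the real one included. In 2 of 100 splits for reprime against naive cells (highest other 6519) the count was as large. So it was in 2 of 100 for H9P against naive cells (highest other 8974). Both shares are under 0.05, which concerns the grouping of these libraries only. Regrouping genotypes stands for no knockdown effect in either state, not for equal effects in both. Splits that kept neither grouping reached at most 6 genes for reprime against naive and 7 for H9P against naive cells. The shares therefore cannot tell whether the effect differs between states. Splits of libraries cannot exclude chance differences between cultures, since the labels do not say whether replicates were separate cultures. The other split of each kept both genotype groupings with a single state mirrored, which is a structure of the samples. For reprime against H9P cells 6 of 100 splits were as large (highest other 7735), and chance was not excluded by that share; all 5 others kept the H9P genotype grouping, and splits that kept neither grouping reached at most 3 genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) gave the largest count in each simple comparison: 7856 genes against a highest other of 34 for naive knockdown, 3069 against 1 for reprime knockdown, 8393 against 2 for H9P knockdown, 13072 against 1 for reprime and naive ctrl, 15483 against 0 for H9P and naive ctrl, and 11059 against 1 for reprime and H9P ctrl.

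Lists were called for a knockdown effect that differed between states, and fewer held with an estimated correlation. Between reprime and naive cells 6 of 12 held, with median differences of 0.13 for cholesterol biosynthesis, -0.89 for fibroblast feeder markers, -0.35 for heat shock genes, 1.69 for mesendoderm markers, 0.91 for primitive endoderm markers and -1.55 for histone genes. The others lost the call with an estimated correlation: -0.20 for DNA methylation machinery, -0.21 for NODAL-activin targets, -0.16 for glycolysis, -0.12 for imprinted genes, 0.10 for mitochondrially encoded mRNAs and -0.11 for the shared pluripotency core. Between H9P and naive cells 5 of 10 held: 0.69 for FGF-ERK targets, 0.31 for cholesterol biosynthesis, -0.45 for heat shock genes, -1.15 for histone genes and -0.44 for the shared core. Those that lost the call had 0.066 for NODAL-activin targets, -0.35 for mitochondrially encoded mRNAs, 0.42 for naive markers, -0.32 for nuclear oxidative phosphorylation and -0.23 for ribosomal protein genes. Between reprime and H9P cells 4 of 12 held: -0.37 for FGF-ERK targets, -0.61 for NODAL-activin targets, -0.64 for feeder markers and 0.14 for heat shock genes. The lost ones had 0.18 for cell cycle genes, -0.23 for cholesterol biosynthesis, 0.47 for mitochondrially encoded mRNAs, -0.57 for naive markers, 0.27 for nuclear oxidative phosphorylation, 0.18 for ribosomal protein genes, 0.20 for the shared core and -0.10 for the stress response. When replicate 2 was the only naive shOGA library, the feeder median between reprime and naive cells was -0.12. Between H9P and naive cells the medians were 0.091 for NODAL-activin targets and -0.19 for mitochondrially encoded mRNAs. Calls were lost for these lists and gained for others, which an arm without replicates cannot weigh. Between reprime and naive cells other medians moved by over 1.5 times with that library alone, to -0.32 for DNA methylation machinery, -0.46 for NODAL-activin targets, -0.059 for imprinted genes and 0.30 for mitochondrially encoded mRNAs.

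Single genes chosen by rule for the size of the difference between reprime and naive cells were NRK (4.47), SPRY4 (3.85), DUSP6 (3.73), SFRP2 (3.29) and TBXT (3.28), with a more positive effect in reprime cells, and HBA2 (-6.33), HBA1 (-6.25), MIR3648-1 (-4.51), RN7SK (-3.87) and MIR3648-2 (-3.74). Between H9P and naive cells they were FRG1FP (9.64), APLN (8.19), BRDT (6.33), KHDC1L (6.27) and BEX5 (6.26), and HBA2 (-7.49), HBA1 (-7.29), RMRP (-6.79), CEND1 (-4.50) and MIR3648-1 (-4.22). Between reprime and H9P cells they were TCEAL5 (3.03), CEND1 (2.92), HAS2 (2.30), PCDHB5 (1.83) and OTX2 (1.63), and FRG1FP (-9.50), KHDC1L (-6.19), BRDT (-5.64), CGA (-5.03) and C3orf56 (-4.30). FRG1FP and CGA had 0 counts in H9P ctrl, and APLN and BEX5 had 0 counts in naive shOGA cells, so their fitted differences depend on the prior count and are no bound. BRDT stood at 163 and 106 CPM in naive ctrl and shOGA cells, 148 and 154 CPM in reprime cells, and 0.793 and 41.4 CPM in H9P cells.

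In H9P cells, genes of chromosome 6 as a whole were higher with shOGA than in ctrl. A few strongly changed genes are argued against, since 95.2% of the 538 genes of chromosome 6 lay above 0. The median stayed at 0.53 over the 490 genes not changed by more than 1. With so few genes left out the median could hardly fall, so that test adds little. Scaling between libraries is argued against, since the median over all 538 genes lay 8.55 median absolute deviations above the other chromosomes. A difference in chromosome number or dose between the H9P cultures may account for it: 100% of the 12 windows had a median above 0.2 (0.42 to 0.69), near the 0.58 of 3 copies against 2. The chromosome 6 level relative to all groups was -0.39 in H9P ctrl, 0.16 in H9P shOGA and between 0.00 and 0.12 in the other groups, so H9P ctrl stood apart, whereas on chromosome 5 H9P shOGA did (-0.28). Whether the knockdown itself or separate culture histories lie behind the difference was untested, since each genotype holds a single set of libraries.

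Globin and leukocyte transcripts stood out in PXGL shOGA replicates 1 and 3, with HBB at 286 and 296 CPM. An effect of the knockdown on globin genes is argued against, since HBB in replicate 2 was 0% of their mean, and library depth is argued against, since depth predicted 14546 HBB counts there and 0% of them were found. RNA of blood cells or another source in these libraries may account for it, since 53.3% (16 of 30) of the other erythroid and leukocyte genes detected were over 2 times higher in both than in replicate 2 and in ctrl. Of those 30 genes 11 also reached 1 CPM in a naive ctrl library, and HBA2 stood at 31.7 and 24.8 CPM in reprime ctrl and shOGA cells, where HBB reached at most 0.174 CPM.

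SPRY4, SFRP2 and 12 other genes of primed cells fell in naive shOGA cells from a median of 2.07% to 0.358% of their primed level. Scaling moves all genes of a library alike, while the 12 genes of low share, chosen without regard to their change, lay up to 4.43 apart. That distance runs from SPRY4 (-3.44), itself among the 14 genes chosen for their fall, to TNC (0.99). With 3883 genes higher and 3973 lower in this comparison, such a spread was near certain beforehand. Scaling is argued against as the whole cause only, and the test cannot tell whether it adds to the fall. Foreign RNA in replicates 1 and 3 stays open: 13 genes chosen again without replicate 2 were all lower in shOGA than in ctrl replicate 2. Their median was -1.63, with 95% limits of -1.91 and -0.69 that reach short of the fall of 1 set against it. Those limits run over genes of a single pair of libraries, taken as independent, and the genes lie near the floor. Fewer primed-like cells in the knockdown culture stays open: 0 of 1758 abundant primed genes lay below 1/3 of that share in naive ctrl cells, as this needs, and the 12 genes of low share had a median of -0.80 in naive shOGA cells, between the values set for and against it, with 8 called lower, 5 of which were among the 14 genes chosen for their fall, and 2 higher, TNC by 0.99 and NRN1 by 0.48. Lower MEK-ERK output within naive shOGA cells stays open as well, with 5 of 18 FGF-ERK targets higher and 5 lower (camera adjusted p = 0.243).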

How the results depend on the processing

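RLE size factors, scaling of each chromosome on its own, PXGL shOGA replicate 2 as the only shOGA library of its state, the O-GlcNAc list without OGA, and mean FPKM of at least 5 for the correlations between knockdown effects were chosen after the data were seen. Under every alternative run, counts of called genes stayed within 1.5 times the value reported, and OGA fell in each state. Across alternatives other than the replicate block, naive knockdown gave 6305 to 8518 genes, reprime knockdown 2229 to 4568 and H9P knockdown 7215 to 9623. Direction was compared only for results called in the main fit or under the alternative. Results called in neither were counted as unchanged whatever their sign. Of the list results, 3510 were unchanged in this sense, 171 lost the call, 63 gained it and 0 reversed. Of the values of single named genes, 12466 were unchanged, 125 lost the call, 113 gained it and 31 reversed. Low counts limit genes near 3 counts per library, where the fold depends on the prior count.

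The replicate numbers do not pair the libraries: the 45 pairs of equal number had correlations of their deviations from -0.187 to 0.155 (mean -0.00259, against 0.00126 for unequal numbers), 3 of them above 0.1, and 5 of 18 libraries were closest to their own number. With the replicate number as a block, edgeR called 7703, 2930 and 8161 genes for the knockdown in naive, reprime and H9P cells, 12881, 15245 and 10850 for the ctrl states and 5730, 7464 and 4885 for the differences of effects; it changed no call of a named gene and added 1 list.

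For the results below the cause was not tested. The number of list calls in the knockdown comparisons was 34, and 19 on FPKM with a pseudocount of 0.1 and 22 with an estimated correlation. With that pseudocount the naive score difference was -0.13 in reprime and 0.50 in H9P cells, the primed score difference -0.018 in naive cells (reversed), 0.20 in reprime and 0.37 in H9P cells. The correlation of the reprime effect with the ctrl difference of H9P from naive cells was -0.0444 with that pseudocount, -0.0606 with limma on FPKM and -0.0520 at mean FPKM of at least 5. The correlation of knockdown effects, in the same order, was 0.0847, 0.0845 and -0.0214 for naive and reprime cells, 0.0900, 0.102 and 0.0878 for naive and H9P cells, and 0.245, 0.284 and 0.277 for reprime and H9P cells, where scaling each chromosome gave 0.0560.

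Scaling each chromosome on its own reversed POU5F1 to -0.11 in reprime and -0.078 in H9P knockdown, to -0.049 in reprime against H9P ctrl and to -0.27 in H9P minus naive effects, CD24 to -0.23 in H9P knockdown, -0.38 in H9P minus naive and 0.16 in reprime minus H9P effects, LIN28B to -0.012 in H9P knockdown and H9P minus naive effects, RPS23 to 0.014 in H9P knockdown and ACAT2 to 0.049 in reprime minus H9P effects. On FPKM, OGT in H9P against naive ctrl reversed to 0.022 with limma, 0.022 with a pseudocount of 0.1, 0.022 without a filter and 0.027 after quantile normalisation. Quantile normalisation reversed MT-ATP8 (0.14) in H9P against naive ctrl and MT-ND4 (-0.046) in reprime minus naive effects. It brought MT-CO3 to 0 in H9P against naive ctrl, which the count of reversals includes. In H9P minus naive effects KLF17 reversed to -0.11 with limma, -0.11 without a filter, -0.18 after quantile normalisation and -0.14 after TMM-type rescaling, and BEX5 to -0.26, -0.26, -0.086 and -0.23. CGA in reprime minus H9P effects reversed to 1.34 with limma, 0.83 with a pseudocount of 0.1, 1.34 without a filter, 1.39 after quantile normalisation and 1.37 after TMM-type rescaling.

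Leaving out each library in turn gave 6897 to 7481 genes for naive, 2229 to 2300 for reprime and 7215 to 7464 for H9P knockdown, 12146 to 12323, 14530 to 14679 and 9860 to 10027 for ctrl reprime against naive, H9P against naive and reprime against H9P, and 5142 to 5955, 6983 to 7722 and 4397 to 4660 for the differences of effects. OGA ranged from -2.25 to -2.07, -1.82 to -1.69 and -1.72 to -1.68, and list calls from 33 to 37. Naive score differences ranged from 0.04 to 0.05 in naive, -0.10 to -0.07 in reprime and 0.25 to 0.39 in H9P cells, and primed ones from 0.08 to 0.12, 0.16 to 0.17 and 0.31 to 0.34. The correlation along the ctrl difference ranged from -0.0135 to 0.0176, and those between effects from 0.000565 to 0.0307 (naive and reprime), 0.0132 to 0.0373 (naive and H9P) and 0.0463 to 0.0714 (reprime and H9P).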

Other observations

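KEGG pathways were chosen for a test after the data were seen. Of 307 pathways, 7 were called among rises and 6 among falls in naive shOGA cells, and 10 and 3 in reprime shOGA cells. In naive shOGA cells, spliceosome genes were among those that rose (49 of 131, 29.8 expected, hypergeometric adjusted p = 0.00572), with proteasome genes (20 of 43, 9.77 expected, 0.0191). Among genes that fell were those of valine, leucine and isoleucine degradation (24 of 46, 10.0 expected, 0.000567), aminoacyl-tRNA synthesis (21 of 44, 9.58 expected, 0.00717) and peroxisomes (31 of 80, 17.4 expected, 0.0165). In reprime shOGA cells cell cycle genes rose (36 of 122, 12.6 expected, 7.11e-07), as in the fixed cell cycle list, and so did genes of p53 signalling (16 of 70, 7.20 expected, 0.0424), although the fixed p53 target list did not pass its test (camera adjusted p = 0.244), while genes of central carbon metabolism fell (16 of 55, 4.77 expected, 0.000983).

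In H9P shOGA cells 38 of 307 pathways were called among genes that rose and 16 among those that fell. The smallest adjusted p among rises were those of leukocyte transendothelial migration (54 of 99, 24.3 expected, hypergeometric adjusted p = 5.06e-08), focal adhesion (81 of 187, 45.9 expected, 2.02e-06) and adherens junction (40 of 72, 17.7 expected, 2.98e-06). Among those that fell were ribosome (75 of 133, 29.2 expected, 5.49e-15), oxidative phosphorylation (64 of 130, 28.5 expected, 2.59e-09) and citrate cycle genes (19 of 29, 6.37 expected, 7.97e-05). The fixed lists of ribosomal protein and nuclear oxidative phosphorylation genes lost their calls in this comparison with an estimated correlation (adjusted p = 0.510 and 0.178). The background was 6590 tested genes with a pathway in the table, and 307 pathways were tested per comparison and direction. Genes of a pathway are not independent, which the hypergeometric test does not take into account.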
